A study of Mus musculus with 7 samples.

How the data were processed

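MeDIP-seq libraries of 1 mouse TS cell line, 1 line of transgene-carrying MEFs and 5 iTSC clones were taken as the authors deposited them, as a table of log2 values per CpG island. Per the labels' protocols, sonicated and adaptor-ligated DNA was immunoprecipitated with an antibody against 5-methylcytosine, duplicate precipitations of a sample were pooled, and the product was amplified by PCR and selected by size. Reads were aligned with Bowtie2 2.2.3 to NCBIM37, per the submitters' processing notes. The counting tool, the definition of the islands and the read filters are not given in the sources used here. Coordinates are those of the table. The table also held 1 further column of values per sample, which was not used.

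The deposited log2 values proved to be whole reads per island times 1 factor per library. In each column 2 to the power of the value, divided by the factor, was within 0.01 of a whole number for 99.9% to 100.0% of islands, and for all islands under 200 reads. The factor was 1 in clone E, 1.34 in TS, 1.26 in MEF, 1.34 in clone A, 1.11 in clone B, 1.15 in clone C and 1.55 in clone D, and an island without reads stood at log2 of 0.9 times the factor. What total the factors were taken from is not given in the sources used here. The recovered reads per library ran from 3572653 in clone D to 6549780 in MEF. Outside the 20 islands with the highest mean over the 7 libraries, 646843 reads remained in MEF, 717146 in clone D, 933534 in clone A, 986681 in TS, 1059709 in clone C, 1219258 in clone B and 1318306 in clone E. Counting error is therefore widest in MEF and clone D.

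Islands were kept when their mean over the 7 libraries was above a log2 value of 3.75, which left out the 4604 lowest (a share of 0.2). Gene names are those of the table. Of the 19722 islands with a name, 17013 matched a current symbol in a RefSeq table of mouse genes and 1774 matched through a synonym. That table was of a later assembly and was used for names only. An island counts as overlapping, upstream or downstream of its gene as the table states.

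The 2 tested comparisons, of the clones with MEF and with TS, were fitted with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3 on the values as deposited, with 7 libraries in 3 groups. The fit had 4 residual degrees of freedom, all from the clones, and a median prior of 21.8. P-values were adjusted by Benjamini-Hochberg over 18416 islands, with a threshold of 0.05. TS and MEF have 1 library each, so that comparison used a rule of size, a log2 difference of at least 1. Each clone was compared with the other 4 in the same way. Gene lists were tested with camera (preset correlation 0.01, and estimated) and fry, with adjustment over 13 lists. Camera asks whether a list moves relative to other islands, and fry whether it moves on balance one way at all. The position of a clone between MEF and TS is the least-squares position over islands that differ by the size rule, and was simulated for libraries equal to TS or to MEF because the choice of islands pulls any other library toward the middle. Chance agreement through a shared control was simulated 50 times with unchanged groups. Where a lone library had 1 to 3 reads the ratio is given with an exact 95% counting interval, and where it had 0 reads as a lower bound at a floor of 3 reads per library.

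The comparisons, the filter, the lists, the alternatives and the rule for named genes were chosen before the data were examined. By that rule each tested comparison names the 10 largest rises and falls with a gene symbol, 1 island per gene, among islands with an adjusted p under 0.05 and all 5 clones on the same side of the lone library. The size-rule comparison names 10 each way. Predicted genes were left out. Also named are the 4 transgene factors, Elf5, Nanog and Pou5f1, up to 4 members of each list with the largest change, and up to 3 islands each way per clone. The lists were the transgene factors and genes of trophoblast, pluripotency, fibroblast and mesenchyme, extraembryonic endoderm, germline, imprinting, Hox, neural and other developmental regulation, tumour suppression and cell cycle, DNA methylation, blood and endothelium, and housekeeping. Some genes stand on more than 1 list.

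The alternatives were no filter, quantile normalization, medians set equal, limma without an intensity trend, stricter thresholds, X- and Y-linked islands left out, each clone left out in turn, other list tests, 1 island per gene, and Spearman correlation. Chosen after seeing the data were limma-voom on the recovered reads with the deposited factors, chromosomes 1, 3, 11 and 14 left out, and the lists without islands named Fgfr2 or Gm20388.

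The procedure was tested on simulated data for the comparison of the clones with MEF, with 200 of 18416 islands changed. It recovered 14.9% of 94 islands changed by 1 log2 and 84.9% of 106 changed by 2, with 8 false calls among 112. The simulated MEF library was set at the level of the clone mean. Many more islands were called in the real comparison, so these shares are not its sensitivity.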

Results

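DNA methylation at CpG islands was measured by MeDIP-seq, in which sonicated genomic DNA is precipitated with an antibody against 5-methylcytosine and the recovered fragments are sequenced. The 7 libraries came from mouse cells. There was 1 library of a trophoblast stem cell line carrying EGFP (TS) and 1 of embryonic fibroblasts carrying viral transgenes under doxycycline control (MEF). The labels do not say whether these fibroblasts had been given doxycycline, so MEF may not stand for untreated cells. The other 5 were induced trophoblast stem cell (iTSC) clones, A to E, made from such fibroblasts. TS cells are the self-renewing progenitors of the placental trophoblast. The transgenes were taken to be Tfap2c, Gata3, Eomes and Ets2, all transcription factors of the trophoblast lineage, from what is known of the study. Values were log2 scaled reads per island, so a higher value means that more methylated DNA was recovered there. The table held 23020 islands with a median length of 925 bp on the NCBIM37 assembly. Of these, 18935 overlapped a gene, 787 lay beside a gene and 3298 had no gene, and 18416 remained after islands of low mean value were left out.

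Reads in islands numbered 5703767 in TS, 6549780 in MEF, 5078062 in clone A, 6149650 in clone B, 4773867 in clone C, 3572653 in clone D and 5508806 in clone E. A single island on chromosome 2, overlapping the predicted gene Gm10800, took 54.2% of them in clone E (95% Wilson interval 54.14% to 54.22%) and 64.1% in MEF (64.07% to 64.15%), the lowest and highest of the 7 shares. The median kept island held 24 reads in MEF and 28 to 48 reads in the other libraries. Counting alone gave an SD of 0.29 log2 at the MEF median. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. No replicate of TS or MEF was analysed, so the p-values measure only the spread between the 5 clones, which the labels do not describe beyond their names, and assume that the lone library varies as the clones do.

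**Figure D1:**
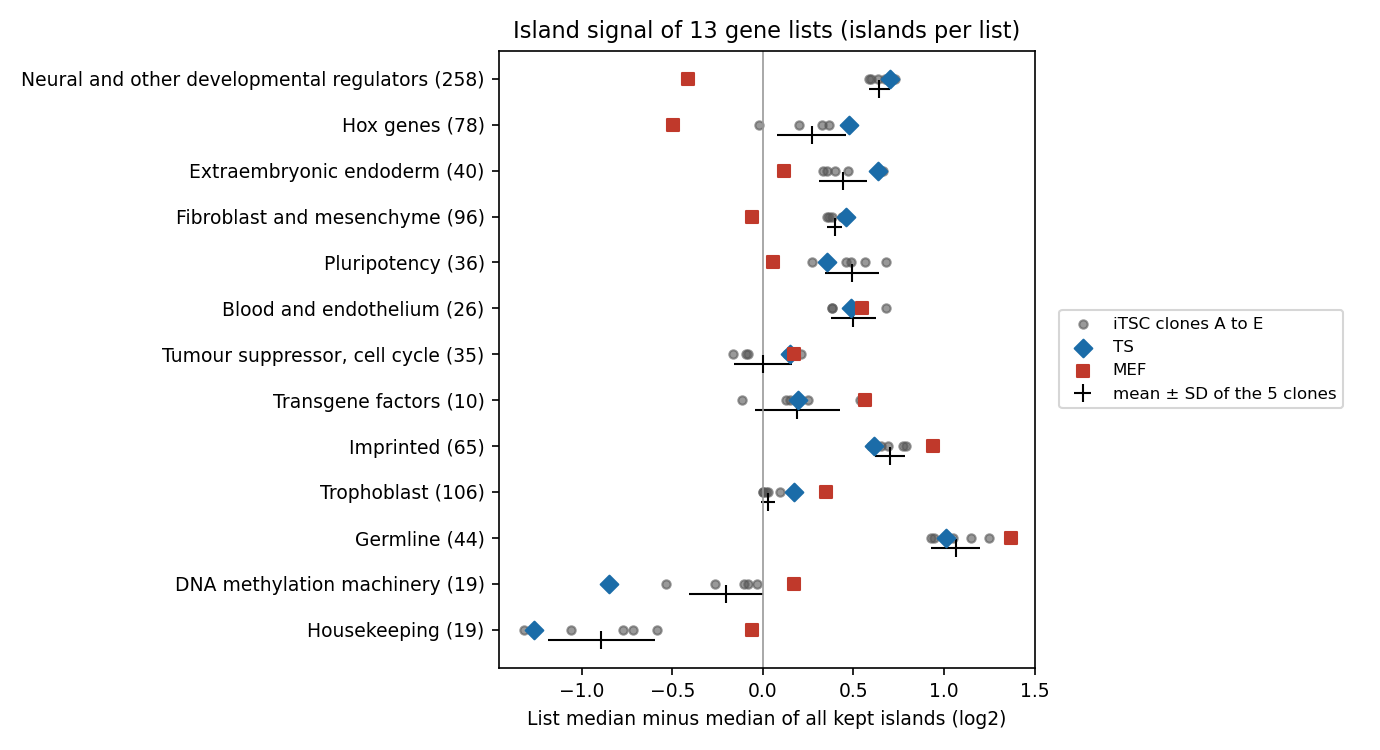
Median island signal of 13 gene lists in each library, as the log2 difference from the median of all kept islands of that library, with the number of islands per list in brackets; diamonds are TS, squares MEF, circles the 5 iTSC clones, and black bars their mean ± SD. Neural regulator islands lay at 0.70 in TS, at -0.42 in MEF and at 0.64 ± 0.06 in the clones.

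The comparison of TS with MEF set out which islands differ between the cell type aimed at and the fibroblasts. Islands of genes that control embryonic patterning were higher in TS. Neural and other developmental regulators lay 0.70 log2 above the library median in TS and at -0.42 in MEF, and Hox genes at 0.47 and -0.50. The largest difference was at the Tbx15 island (chromosome 3, 99044617 to 99045622), which encodes a T-box factor of mesenchyme, with 72 reads in TS and 1 in MEF, a 76.5-fold ratio (95% counting interval 13.3 to 3061). Islands of Mmd2, Pdgfrl, Myl9 (a myosin light chain), Anp32a, Hpse2, Aadat, Batf and Gng8 also had 1 read in MEF and 35 to 53 in TS, and that of the homeobox gene Hmx1 had 2 and 69. The islands of the homeobox genes Gbx2 and Nkx6-1 had 0 reads in MEF and were at least 8.49-fold and at least 7.79-fold higher in TS, at a floor of 3 reads per library.

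Fewer islands were higher in MEF. Marveld2, which encodes a tight junction protein, had 6.47 log2 in MEF and 3.23 in TS, and Esrrb, an orphan nuclear receptor needed by TS cells, had 6.07 and 3.23. The cyclin gene Ccnd3 differed by -3.08 (TS minus MEF) and the endosome tether gene Eea1 by -2.77. Islands of Ildr1, Tnpo1, Pkn2, Rad9 and H2-Q8 had 2 reads in TS, and that of Vps33a had 3. Their MEF to TS ratios ran from 8.0-fold for H2-Q8 (1.90 to 71.4) to 13.2-fold for Ildr1 (3.32 to 114). By the rule of a log2 difference of at least 1, 5909 islands were higher in TS and 859 higher in MEF (87.3% higher in TS). The median island was 0.50 higher in TS as deposited, but the median difference was -0.15 with quantile normalization. With library medians set equal the split was 3322 to 3088 (51.8% higher in TS) and with quantile normalization 3439 to 2367 (59.2%). With 1 library each no p-value was computed.

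The comparison of the clones with MEF asked what differed after reprogramming. Islands of developmental regulators lay at 0.64 ± 0.06 log2 from the library median in the clones against -0.42 in MEF. Single islands with the largest rises included Tbx15 (chromosome 3, 99044617 to 99045622), at 6.24 ± 0.42 log2 in the clones (SD, n = 5) with 1 read in MEF, a 63.9-fold ratio (95% counting interval 11.4 to 2530). They also included Shh (chromosome 5, 28789311 to 28790054), which encodes a morphogen, at 41.3-fold (7.33 to 1637), and Dmrt1 (chromosome 19, 25679053 to 25679735), a regulator of testis development, at 37.3-fold (6.61 to 1479). The fold was 60.1 for Mmd2, 46.4 for Myl9, 43.9 for Pdgfrl, 43.7 for Anp32a, 39.0 for the BMP antagonist gene Sostdc1 and 35.6 for the protocadherin gene Pcdh18, each against 1 MEF read and with a lower bound of 6.30 or more. Skor2, with 0 reads in MEF, was at least 10.9-fold higher. All 10 had an adjusted p of 1.5e-09 or less in limma, and all 5 clones lay above MEF at each. Of the islands called higher, 294 had 3 reads or fewer in MEF.

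Among neural and other developmental regulators, 212 of 258 islands rose and none fell (222 and 0 adjusted over the list alone). Nkx6-1 and Gbx2 were at least 9.95-fold and at least 6.72-fold higher than MEF. Nkx2-2 had a ratio of 23.8 (6.51 to 197) and Pax7, a gene of muscle precursors and neural crest, of 16.4 (5.55 to 80.1). Of the 78 Hox islands, 60 rose and none fell (64 and 0 adjusted over the list alone). Hoxc4 had a ratio of 33.1 (5.86 to 1314), Hoxc12 of 18.4 (3.23 to 736) and Hoxa10 of 9.79 (2.64 to 81.9), and Hoxc13 rose by 3.20 log2 (SE 0.33, adjusted p = 4.1e-08). The neural list had 158 islands higher and 5 lower with medians set equal and the Hox list 35 and 1. The median island was 0.49 higher in the clones as deposited, but its difference was -0.13 with quantile normalization. Relative to the median island as deposited, the list medians were 1.29 and 0.83. The first stayed at 1.29 with its 3 islands at 0 MEF reads put at the floor.

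Fibroblast and mesenchyme genes had 51 of 96 islands higher and none lower (56 and 0 adjusted over the list alone). Examples were Tcf21 at 13.9-fold (4.71 to 68.1), Tbx5 at 12.5-fold (3.41 to 105) and Prrx1, a homeobox gene of limb mesenchyme, at 9.89-fold (2.67 to 82.7). Extraembryonic endoderm genes had 20 of 40 islands higher (24 adjusted over the list alone). Among them Sox17 rose by 3.23 log2, Gata4 by 2.74 and the laminin gene Lamb1 by 2.23, and Pdgfra had a ratio of 8.11 (2.71 to 39.9). Pluripotency genes had 17 of 36 islands higher (18 adjusted over the list alone), among them Otx2 with a rise of 3.86 log2 and Tet1, which encodes an enzyme that oxidises 5-methylcytosine, with a rise of 2.98 (SE 0.32, adjusted p = 7.1e-08). A second Tet1 island, at 62348736 on chromosome 10, changed by -0.38. Nr5a2 had a ratio of 23.2 (4.09 to 924) and Foxd3 of 16.3 (2.86 to 653). The median over all islands subtracted, these 3 lists lay at 0.48, 0.56 and 0.18. The fibroblast list had 36 islands higher and 3 lower with medians set equal, the endoderm list 12 and 1 and the pluripotency list 12 and 2.

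Camera with its preset correlation gave these lists an adjusted p of 9.6e-26 (neural), 6.0e-09 (Hox), 1.7e-05 (fibroblast), 0.0075 (endoderm) and 0.010 (pluripotency). With an estimated correlation the adjusted p was 0.36 (neural and fibroblast), 0.38 (Hox and endoderm) and 0.40 (pluripotency), so none of these calls held. Housekeeping genes were lower relative to other islands (median -0.52, adjusted p = 0.0047, and adjusted p = 0.36 with an estimated correlation), although 1 of their 19 islands, at the ubiquitin gene Ubc, was called higher by 1.92 log2, a call lost when medians were set equal (the adjusted p of Ubc ran from 1.5e-06 to 0.060 over its alternatives). Over their alternatives, the adjusted p ran from 1.9e-30 to 0.36 (neural), 1.2e-10 to 0.38 (Hox), 7.1e-08 to 0.36 (fibroblast), 0.00036 to 0.38 (endoderm), 0.00077 to 0.41 (pluripotency) and 0.0011 to 0.92 (housekeeping). With 1 island per gene the pluripotency list was also not called (adjusted p = 0.41).

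Trophoblast genes moved both ways. Of their 106 islands, 32 rose and 6 fell (37 and 7 adjusted over the list alone), against 18 and 15 with medians set equal and 20 and 17 with quantile normalization. The list median relative to all islands was -0.01 and its mean -0.18, with an adjusted p of 0.39. Islands named Fgfr2, after the FGF receptor gene of TS cells, rose by up to 3.69 log2 (chromosome 7, 138695682 to 138696376). This name stood on 37 islands spread over 2912605 bp, and was taken as the table gives it. Whether these islands lie at that gene was not checked, so their values may not describe it. Those of them that were kept are among the 106 islands of the list. Without islands named Fgfr2 or Gm20388 the list was likewise not called. The Cdx2 island (chromosome 5, 148113246 to 148113658), at a homeobox gene of the trophoblast lineage, rose by 2.81 (SE 0.33). An island listed for 1700108N11Rik, a name matched through a synonym to the zinc finger gene Ovol2, rose by 2.99.

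The largest falls against MEF also included trophoblast genes. The island of Krt7 (chromosome 15, 101242548 to 101243394), an epithelial keratin gene of trophoblast, fell by 2.84 log2 (SE 0.45, adjusted p = 1.7e-05), to 4.01 ± 0.63 in the clones from 6.85 in MEF. Hand1 (chromosome 11, 57644637 to 57645621), which encodes a factor needed for trophoblast giant cells, fell by 2.33 (SE 0.46, adjusted p = 0.00026). Cldn6, a claudin gene, fell by 2.21 (SE 0.65, adjusted p = 0.0096) and Esrrb fell by 1.96 (SE 0.49, adjusted p = 0.0025). Marveld2 fell by 2.71 and the other 5 were Mmp28 (-2.14), Sh2d5 (-2.07), Slc5a10 (-2.05), Crlf2 (-1.87) and Fbxo6 (-1.83). All 5 clones lay below MEF at each of these 10 islands. TS had 4.59 at Hand1, 3.75 at Cldn6 and 3.23 at Esrrb, where limma called no difference from the clones, and 6.45 at Krt7.

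Imprinted genes had 18 of 65 islands higher and 2 lower (the same counts adjusted over the list alone), with Kcnq1 higher by 2.16 log2, Dlk1 by 1.93 and Zim1 by 1.80, and Peg12 (-1.68) and Mkrn3 (-0.99, named after its value was seen) lower. With medians set equal 3 islands of the list were higher and 4 lower, and Zim1 was not called (its adjusted p ran from 0.00085 to 0.074). Germline genes that are methylated in most somatic cells had 5 of 44 islands higher and none lower, also adjusted over the list alone, among them 1700019N12Rik at 2.16, Ccdc79 at 1.5 and Tdrd6, a piRNA pathway gene, at 1.43. With medians set equal that became 3 and 3. Among DNA methylation genes 1 of 19 islands rose, a Tet1 island (chromosome 10, 62328164), also adjusted over the list alone. Another Tet1 island, at 62348736, changed by -0.38. The transgene factor list had 4 of 10 islands higher, as also adjusted over the list alone, and 1 higher and 1 lower with medians set equal. Camera called none of these 4 lists (adjusted p = 0.82, 0.54, 0.32 and 0.85), but with quantile normalization the germline list was lower (adjusted p = 0.027, range over its alternatives 0.027 to 0.92). The imprinted list had a median of 0.03 and a mean of -0.14 relative to all islands, with a negative camera direction.

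Over all islands, 5563 were called higher and 99 lower in the clones than in MEF (98.3% higher), with 7073 at an unadjusted p under 0.05. The trophoblast, imprinted, germline and DNA methylation lists had no larger a share called higher than these 5563 of 18416. With medians set equal the split was 2797 to 813 (77.5% higher) and with quantile normalization 3177 to 1064 (74.9%). There were 2795 islands called higher and 87 called lower under all 3 scalings.

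**Figure D2:**
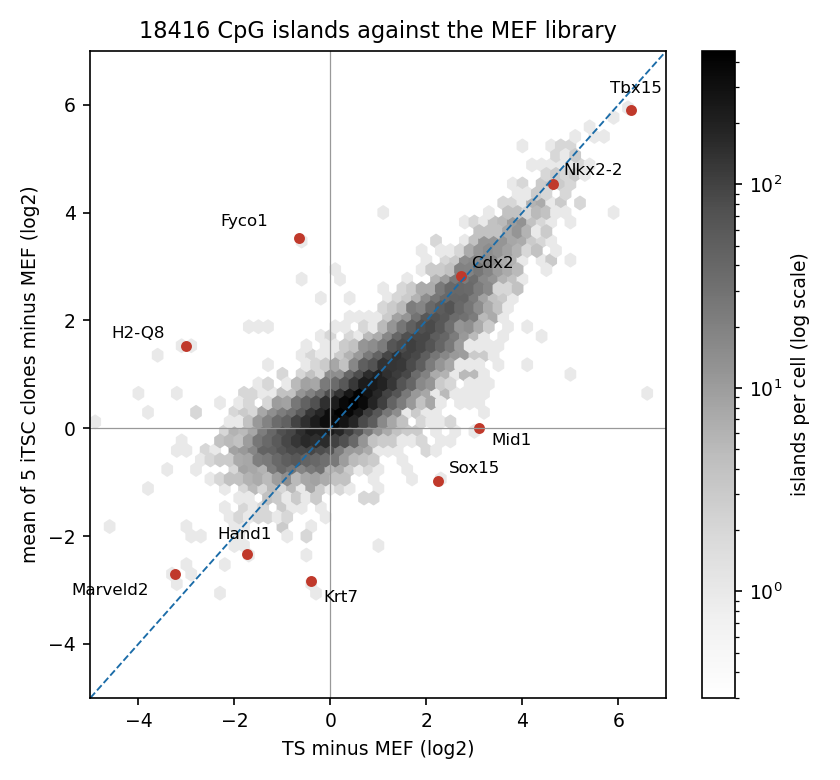
Difference of each of 18416 islands from MEF on the log2 scale, for TS (horizontal axis) and for the mean of the 5 iTSC clones (vertical axis); shading is the number of islands per cell on a log scale, the dashed line marks equality, and red points are named islands. Most islands follow the dashed line, while Fyco1 and H2-Q8 lie above it and Mid1, Sox15 and Krt7 below it.

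The comparison of the clones with TS asked what still differed from the cell type aimed at. By limma 205 of 18416 islands did. The X-linked island of Mid1 (166434713 to 166436290), a ubiquitin ligase gene, fell by 3.10 log2 (SE 0.29, adjusted p = 1.3e-07), to 6.56 ± 0.23 (SD, n = 5) from 9.66 in TS, and MEF had 6.57. The island of Ptch1, the Hedgehog receptor gene, fell by 2.69 (SE 0.37, adjusted p = 7.6e-05), to 4.91 ± 0.43 from 7.6, and MEF had 4.51. Fam19a5 fell by 2.85 (SE 0.39, adjusted p = 7.6e-05) and Krt7 fell by 2.44 (adjusted p = 0.0040). The other named falls were at Sox15, a Sox family gene (-3.22), the metalloproteinase gene Mmp28 (-3.09), Irak1bp1 (-2.55) and Acad11 (-2.52).

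Rises against TS included H2-Q8, a class I histocompatibility gene, at 25-fold (6.85 to 207) against 2 TS reads, and Fyco1 at 19-fold (6.44 to 92.5) against 3. Vps33a and Ccr9, a chemokine receptor gene, had ratios of 13.8 (4.68 to 67.6) and 13.9 (3.78 to 116), Lars2 of 10.2 (2.76 to 85.3) and Obfc2a of 8.50 (2.29 to 71.2). The phosphoinositide phosphatase gene Sacm1l rose by 3.34 log2 (SE 0.34, adjusted p = 4.5e-07), Phldb3 by 3.12 (SE 0.36, adjusted p = 5.6e-06) and Ppfia3 by 3.0 (SE 0.31, adjusted p = 7.3e-07). Of the islands called higher, 24 had 3 reads or fewer in TS, where the p-values carry the same limit as at few MEF reads. Named falls lost by some alternatives were Dyx1c1 (-2.79), D10Bwg1379e (-2.78) and Btd (-2.76), with adjusted p of 0.031, 0.016 and 0.014. Over their alternatives these ran from 0.00013 to 0.20, from 2.8e-05 to 0.10 and from 0.00011 to 0.066, and all 3 calls were lost with quantile normalization and without the intensity trend.

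In all, limma called 96 islands higher and 109 lower than in TS, with 2211 at an unadjusted p under 0.05. Without clone E the count rose from 205 to 486 (205 higher, 281 lower), and with quantile normalization it was 120 (63 higher, 57 lower). The voom fit on recovered reads called 38 higher and 168 lower, and the fit without an intensity trend 82 and 47. Under all 3 scalings 46 islands were called higher and 53 lower.

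By list, Hox islands lay lower in the clones than in TS (median relative to all islands -0.23, camera adjusted p = 0.0013), as did the neural list (-0.16, adjusted p = 0.0014). With an estimated correlation the adjusted p was 0.93 for both. Relative to the mean of the clones, TS was higher by 0.35 over chromosome 11 and by 0.35 over chromosome 1. Hoxb9 (-1.40), Hoxb8 (-1.24) and Hoxb3 (-1.01), among the largest Hox falls, lie on chromosome 11, and Hoxd11 (-1.06) on chromosome 2. Lhx4 and Lhx9 of the neural list lie on chromosome 1 and Otx1 on 11, but Uncx on 5. The lists were not retested without these chromosomes. Part of both differences may come from the chromosome shifts. No single Hox island of 78 was called, in limma or adjusted over the list alone. In the neural list 2 of 258 fell (4 adjusted over the list alone), Lhx4 (-1.51, adjusted p = 0.0048) and Uncx (-1.29, adjusted p = 0.046), the second lost under several alternatives (0.0035 to 0.14). DNA methylation genes lay higher (0.20, adjusted p = 0.0078, and adjusted p = 0.36 with an estimated correlation) with 2 of 19 islands called, also adjusted over the list alone. Both lay at Dnmt3a, a de novo methyltransferase gene, and the island with the larger change (chromosome 12, 3891773 to 3892224) rose by 2.33 (SE 0.49, adjusted p = 0.013). That call was lost with quantile normalization and voom (adjusted p from 0.00047 to 0.11). Housekeeping genes lay higher as a list (0.36, adjusted p = 0.045, and adjusted p = 0.86 with an estimated correlation) with no island called in limma, a call lost without a filter, with both other scalings and without clone A, C, D or E.

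With an estimated correlation none of these 4 calls held, and fry called none of these lists. Over their alternatives the adjusted p ran from 0.00012 to 0.93 (Hox), 0.00013 to 0.93 (neural), 0.0035 to 0.36 (DNA methylation) and 0.031 to 0.86 (housekeeping). With 1 island per gene the Hox, DNA methylation and housekeeping calls were lost (adjusted p = 0.060, 0.18 and 0.060).

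The other lists were not called against TS. In the trophoblast list 2 islands rose and 2 fell (5 and 4 adjusted over the list alone; adjusted p = 0.75), the falls being Krt7 and an island named Fgfr2 (chromosome 7, 139507047) at -2.21. The pluripotency list had 1 fall, Lefty2 at -1.22 (2 adjusted over the list alone; list adjusted p = 0.86). The fibroblast list had 1, the collagen crosslinking gene Lox at -1.33 (also 1 adjusted over the list alone; 0.30), and the imprinted list 1, Igf2 at -1.86 (1 rise and 3 falls adjusted over the list alone; 0.75). The endoderm list had 1 rise, Pth1r at 1.38 (also 1 adjusted over the list alone; 0.86). Each of these last 4 islands was lost in 2 or more alternatives, and the highest adjusted p was 0.16 for Lefty2, 0.095 for Lox, 0.16 for Igf2 and 0.20 for Pth1r. Relative to all islands the pluripotency list had a median of 0.08 and a mean of -0.02 and the imprinted list of 0.02 and -0.04, with a negative camera direction for both. No germline island was called, in limma or adjusted over the list alone, and the list had an adjusted p of 0.81.

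Islands of the 4 transgene factors were read in every library. Gata3 had 5 kept islands, and at one inside the gene (chromosome 2, 9798503 to 9799445) TS had 5 reads, MEF 36 and the clones 127, 36, 32, 16 and 118 from A to E. The rise against TS was 3.14 log2 (SE 0.60, adjusted p = 0.0049). At the island overlapping Eomes (chromosome 9, 118387426 to 118389080) TS had 10 reads, MEF 37, clone A 176 and the other clones 33 to 52. The rise against TS was 2.39 (adjusted p = 0.017). Both calls were lost with quantile normalization, without the intensity trend and with voom, with adjusted p from 4.2e-08 to 0.18 and from 3.0e-07 to 0.30. The island overlapping Tfap2c, listed as Tcfap2c, had 5.98 log2 in TS, 6.38 in MEF and 6.98 ± 0.16 in the clones (adjusted p against TS = 0.098), and was called higher with medians set equal and with quantile normalization (0.019 to 0.19 over its alternatives). The Ets2 island had 4.42 in TS, 5.47 in MEF and 4.75 ± 0.41 in the clones (adjusted p against MEF = 0.20), and was called lower than MEF under both other scalings (0.018 to 0.27).

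The Eomes island downstream of the gene (118385676 to 118386373) had 32 reads in TS and 3 in MEF, and the clones were 4.69-fold (1.54 to 23.3) above MEF. The Gata3 island at 9795923 rose by 1.15 log2 against MEF (adjusted p = 0.0035), a call lost with both other scalings (0.0016 to 0.17). Against TS the transgene list had 2 islands higher and none lower (4 and 2 adjusted over the list alone) and was not called (adjusted p = 0.16). It was called without clone D (0.043), without clone E (0.022) and with 1 island per gene (0.00042), within a range of 0.00042 to 0.93 over its alternatives. No island was named for Elf5, Nanog or Pou5f1, so no value is given for these genes.

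How far each clone had moved from the MEF to the TS pattern was measured as its position on the line from MEF at 0 to TS at 1. Over islands higher in TS the clones stood at 0.842 ± 0.057 (SD, n = 5), between 0.760 in clone D and 0.915 in clone B. Clone D also had the fewest reads outside the 20 highest islands (717146) and the lowest median value (5.44). Clone B had the highest median (5.64), while clone E, with the most such reads (1318306), stood at 0.861. Differences between clones in position were therefore not separated from differences between their libraries. A simulated library equal to TS gave 0.956 and one equal to MEF 0.0442. Over islands higher in MEF the clones stood at 0.236 ± 0.113, from 0.0858 in clone C to 0.382 in clone B, against simulated values of 0.833 and 0.163. This second value depended on the scaling. It was 0.523 ± 0.122 with medians set equal and 0.590 ± 0.053 with quantile normalization, where the first value was 0.818 ± 0.034 and 0.856 ± 0.033. The exact two-sided sign-flip test against the midpoint gave p = 0.063 for both values as deposited, which is the smallest that 5 clones allow, and p = 0.75 for islands higher in MEF with medians set equal. With quantile normalization all 5 clones lay on the other side of the midpoint for these islands, from 0.523 to 0.662 (exact sign-flip p = 0.063).

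**Figure D3:**
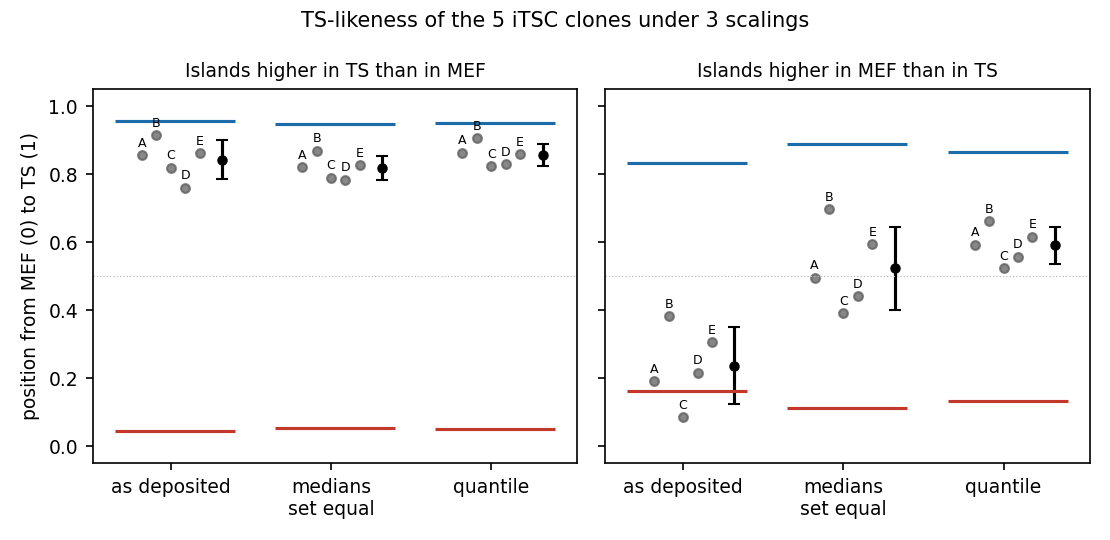
Position of each iTSC clone (labelled circles) between MEF (0) and TS (1), for islands higher in TS (left) and higher in MEF (right), under 3 scalings; black points are the mean ± SD of 5 clones, and the upper and lower lines mark simulated libraries equal to TS and to MEF. The clones lie at 0.842 on the left as deposited, and on the right they move from 0.236 as deposited to 0.590 with quantile normalization.

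Across the kept islands, which are not independent replicates, the clones had a Pearson r of 0.872 ± 0.017 with TS, 0.663 ± 0.027 with MEF and 0.906 ± 0.005 with each other (SD, n = 5), and TS and MEF had 0.584. All 5 clones correlated better with TS than with MEF, by 0.208 ± 0.041 (exact sign-flip p = 0.063, the smallest possible). The difference was 0.131 with no filter on low values. Of the islands called higher in the clones than in MEF, 4758 of 5563 were also higher in TS by the size rule, where independent lists would share 1785. Of those called lower, 43 of 99 were also lower in TS, against 4.62. With medians set equal these overlaps were 2427 of 2797 (against 505) and 505 of 813 (against 136). The differences of the clones and of TS from MEF had r = 0.881 and a covariance of 0.914, where unchanged groups simulated against the same MEF library gave 0.647 and 0.122. The covariance difference was 0.792. Taken against the shared TS library, the differences of the clones and of MEF had r = 0.612 and a covariance of 0.380, where unchanged groups gave 0.646 and 0.122 (covariance difference 0.259). Part of these overlaps and covariances may come from the shared library, which cannot be split.

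The clones were also compared with each other, each against the other 4, as a background for tests with a lone library. Clone E had 51 islands higher and 72 lower, clone A 10 and 5, clone C 0 and 1, the last at the predicted gene A530083I20Rik (-2.25). In clones B and D limma called none, with 989 and 1080 at an unadjusted p under 0.05. In clone A the islands of Prmt6, an arginine methyltransferase gene, Blcap and Sox21 rose by 3.0, 2.99 and 2.78 log2, and that of Taf1 on the X fell by 2.76. The other 4 falls in clone A were at islands without a gene, and its rises included the Eomes island at 118387426 (2.19, adjusted p = 0.00044), named after its value was seen. In clone E Fgfr4 rose by 3.06, the X-linked Pqbp1 by 2.96 and Srebf1, a regulator of lipid synthesis, by 2.30, while falls were at Slc45a1 (-3.45), the growth factor gene Hbegf (-3.25) and Fam5b (-3.05). Of the 51 rises in clone E, 17 lay on chromosome 11, where Srebf1 lies, and 11 on the X, while none of its falls did. The total of 139 was 74 with no filter and 48 with quantile normalization.

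Several libraries were shifted over whole chromosomes. Relative to the other clones and to its own autosomal median, clone E was higher by 0.50 log2 over the 1557 kept islands of chromosome 11 (95% bootstrap interval 0.49 to 0.53), and clone A by 0.41 over chromosome 14 (0.38 to 0.43), where Sox21 lies. Relative to the mean of the clones, TS was higher by 0.35 on chromosome 11 and by 0.35 on chromosome 1, lower on chromosome 3 (-0.20), and higher on the X by 0.24 (0.18 to 0.27). The X was also shifted in clones B (0.18), C (-0.16), D (-0.14) and E (0.15). Calls between the clones and TS were uneven over chromosomes. On chromosome 11, which holds Sox15 and Mmp28, 1 island was called higher and 17 lower than in TS, on chromosome 1, which holds Lefty2 and Lhx4, 2 higher and 15 lower, and on chromosome 3, 14 higher and 1 lower. Chromosome 12, with no such shift in TS (-0.003), was as uneven, at 10 higher and 1 lower. With chromosomes 1, 3, 11 and 14 left out, an alternative added after the data were seen, 79 islands were called higher and 81 lower than in TS.

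**Figure D4:**
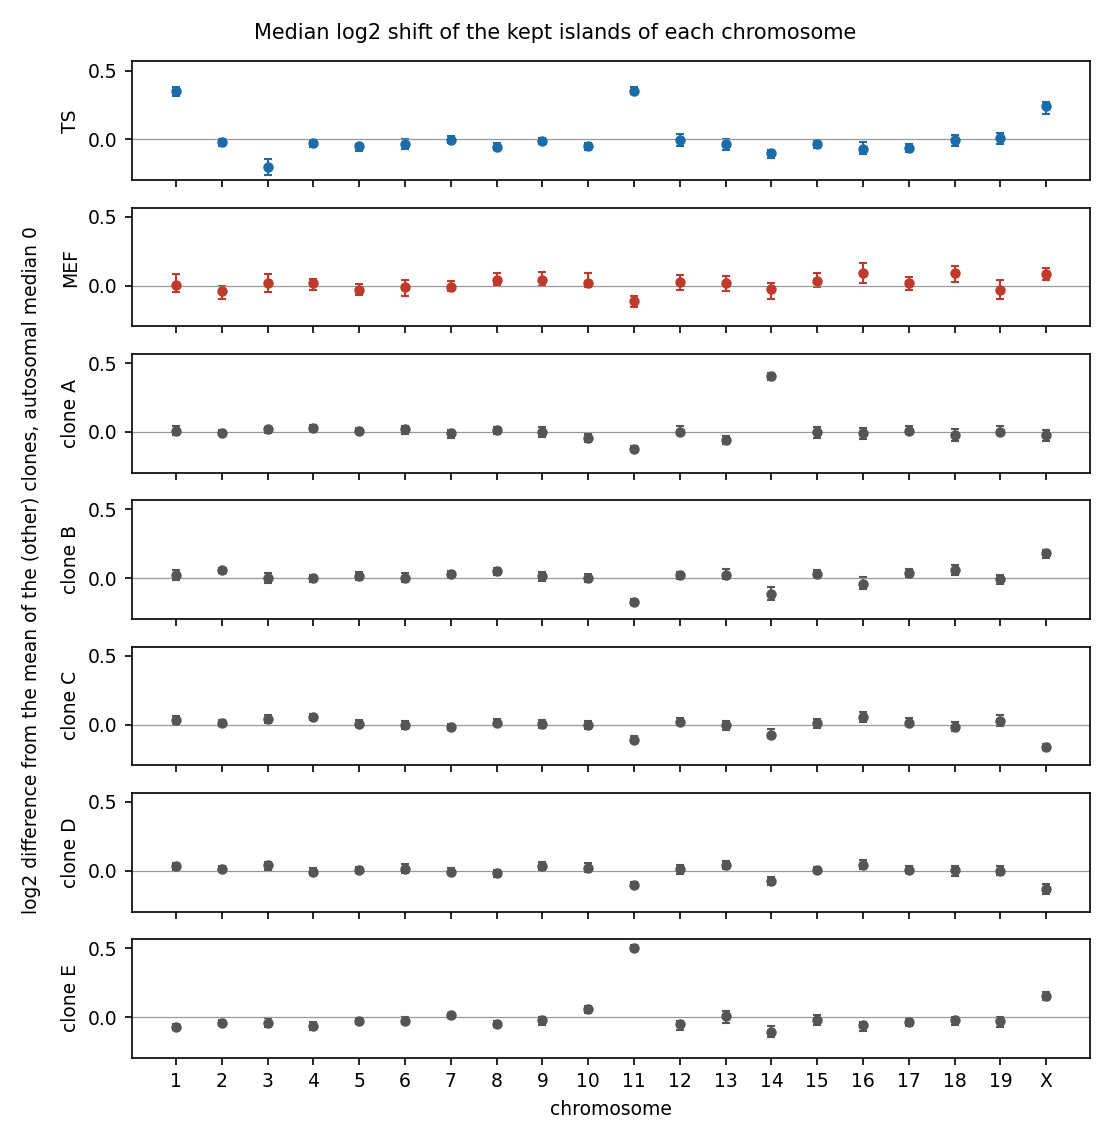
Median log2 shift of the kept islands of each chromosome, with 95% bootstrap intervals, for TS and MEF against the mean of the 5 clones and for each clone against the other 4, each relative to its own autosomal median. Chromosome 11 stands out in clone E (0.50) and TS (0.35), chromosome 14 in clone A (0.41) and chromosome 1 in TS (0.35).

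The 482 kept X-linked islands were described apart, since methylation of the inactive X raises their signal in female cells. Their median lay 0.54 log2 above that of autosomal islands in both TS and MEF, and 0.35 ± 0.13 above in the clones (SD, n = 5), at 0.29, 0.47, 0.23, 0.24 and 0.51 from A to E. The median difference of X-linked islands from MEF, minus that of autosomal islands, was -0.09 ± 0.14 over the clones, within their spread, and the same difference from TS was -0.20 ± 0.13. The labels give no sex for any of the cells. Y-linked islands had 345 reads in MEF and 1 to 5 in each other library, so the MEF library held cells with a Y chromosome. The clones gave almost no Y-linked reads, so MEF may differ in sex from the cells they were made from. An X-linked difference from MEF may therefore reflect the sex of the cells rather than a change on reprogramming. Male cells would lower the X-linked signal of MEF, but its level of 0.54 lay above that of all 5 clones. The difference from MEF was positive in clones B (0.06) and E (0.04) and negative in A, C and D.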

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

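The tests of explanations in this part were all chosen after the results were seen. Of 88 sets of 5 clone values, 9 held a clone far from the others, where chance gives about 1 in 20, or 4.4. At named islands, the Ccr9 island stood at 4.34 log2 in clone D and at 5.23 to 5.54 in the others. The Cldn6 island stood at 2.00 in clone E against 3.90 to 4.05. The Slc5a10 island stood at 4.23 in clone B against 5.09 to 5.43. The D10Bwg1379e island stood at 5.63 in clone A against 3.17 to 3.79. The Eomes island at 118387426 stood at 7.88 in clone A against 5.67 to 5.73. Small shifts in clone E stood apart on chromosome 1 (-0.0722, others 0.01 to 0.04) and chromosome 5 (-0.0298). Shifts are relative to the autosomal median of the clone, which in clone E includes the raised chromosome 11. Both small shifts may follow from that. The Y-linked islands, which the comparisons do not use, had 345 reads in MEF, in 7 of 9 islands, and 1 in TS, 2 in clone A, 4 in clone B, 5 in clone C, 2 in clone D and 1 in clone E.

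Chromosome 11 in clone E (0.50, others -0.17 to -0.10) and chromosome 14 in clone A (0.41, others -0.11 to -0.08) were the clone shifts farthest from the rest, and TS was shifted on chromosomes 1, 3 and 11 and on the X (0.241), which the sex of the cells can move and for which no explanation was tested. A library bias toward chromosomes dense in islands is argued against, since the likewise dense chromosomes 5, 7, 17 and 19 had a median shift of -0.0300 in clone E and -0.0261 in TS. A change in chromosome dosage may account for the shifts other than that of chromosome 3, since the islands left out as low, which carry little methylation signal, moved the same way and by more than on any autosome whose kept islands shifted by less than 0.1. Their shift was 0.614 (95% bootstrap interval 0.550 to 0.678) for chromosome 11 in clone E, 0.326 for chromosome 14 in clone A, 0.252 for chromosome 11 in TS, 0.335 for chromosome 1 in TS and -0.162 for chromosome 3 in TS. On the autosomes without such a shift it ran from -0.140 to 0.0931 in clone E, from -0.168 to 0.120 in clone A and from -0.200 (chromosome 12) to 0.110 in TS, with intervals that left out 0 on 10 of 17, 3 of 17 and 2 of 16 of them. For chromosome 3 in TS dosage therefore cannot be told apart from such variation. Copy number itself was not measured, and a methylation change over a whole chromosome stays open.

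At one island of each transgene factor gene, MEF and the clone mean both exceeded TS. The smaller of the 2 differences, at the island where it was largest, was 2.76 log2 at Gata3, 1.80 at Eomes, 0.40 at Tfap2c and 0.33 at Ets2. In limma the clones did not differ from TS at the islands of Tfap2c (adjusted p = 0.098) and Ets2 (adjusted p = 0.84), where clones A (4.33) and D (4.33) lay below TS (4.42). At the other 4 kept islands of Gata3 MEF lay below TS (6.49 against 6.67, 5.55 against 6.18, 5.34 against 6.73 and 5.09 against 6.82). The mean of 1.32 was reached by 0.01% of 10000 random sets of 4 genes with the same numbers of islands (permutation p = 0.000200, against a random median of -0.33). That test was prompted by the values at Gata3 and Eomes, and the excess at Tfap2c and Ets2 was small. Reads from the transduced copies of the factors are a candidate source, since MEF and the clones both carry them and TS does not. Methylation of the endogenous islands cannot be told apart from it: the islands beside Eomes did not share the excess (median -2.53), but methylation can change at a single island. Whether the excess reads end at exon borders, as copies without introns would give, was not tested.

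As deposited, MEF had a lower signal than the clones over most islands, with a median difference of 0.49. With quantile normalization the median difference was -0.13, so the general shift depended on the scaling, and what follows concerns the deposited values. A single scaling factor that is too low for MEF is argued against as the whole cause, because the 19 kept housekeeping islands differed by -0.0321 (95% bootstrap interval -0.22 to 0.21, which takes islands as independent). Weaker recovery of methylated islands in the MEF library could account for the general shift, since germline and imprinted list islands differed by 0.479 (0.41 to 0.56). In MEF these lists lay 1.37 and 0.94 log2 above the library median. Their islands were taken by gene name, so methylation of each in most cell types is not established. A loss of recovery equal at all methylated islands would not account for developmental regulators. Hox and neural islands exceeded germline and imprinted islands by 1.16 (1.02 to 1.33, islands again taken as independent). A loss that differs between islands was not tested, so weaker recovery is not excluded for them. A higher methylation of developmental islands in the clones and TS than in MEF is the biological explanation that stays open for that part, and with 1 MEF library a difference between cell types and between libraries is not separated.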

How the results depend on the processing

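The alternatives chosen after seeing the data in this part were voom, the chromosomes left out and the lists without Fgfr2 and Gm20388. Other size factors and prior counts, planned for a deposited table of counts, and pseudocounts, planned for counts or linear values, were not run, since the deposited values are log2. No paired analysis was possible because TS and MEF have 1 library each. With no filter the correlation difference was 0.131 and the clone comparisons called 74 islands. Quantile normalization gave 120 islands between clones and TS, 48 between clones, and a position of 0.590 over islands higher in MEF. With medians set equal that position was 0.523 and 3610 islands differed between clones and MEF. Between clones and TS the fit without an intensity trend called 129, an adjusted p under 0.01 gave 82 (72 between clones), and leaving out a clone gave 139 to 486. A log2 difference of at least 2 left 2432 islands between TS and MEF. For the lists, camera with an estimated correlation called 0 against MEF and 0 against TS, fry 10 and 0, and 1 island per gene 2 against TS. Against MEF fry turned the direction of the trophoblast (adjusted p = 0.0039), imprinted (0.025), tumour suppressor (0.0092), DNA methylation (0.025) and housekeeping (0.92) lists to higher, and that of the germline list, called by neither test (0.11). Fry does not compare a list with other islands, so it includes the general shift from MEF. For the other differences the cause was not tested. Voom called 4524 islands against MEF and 206 against TS. Over all alternatives, list results kept their side of the threshold in 303 cases (15 of these changed direction while called neither way), lost the call in 25, gained it in 5 and turned with a call in 5. For named islands these were 2996 (89), 90, 38 and 0 cases. Leaving out clone A, B, C, D or E lost 2, 5, 7, 3 and 0 island calls and, for all but clone B, the housekeeping call against TS. Depth sets a counting SD of 0.29 log2 at the 24 median reads of MEF. The simulation, with 200 islands changed, recovered 14.9% of changes of 1 log2, which is not the sensitivity of the real comparison. How much of that is due to depth was not tested.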

Other observations

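The permutation test of clustering in this part was chosen after the results were seen, and the tests of gene lists and single islands were planned. Tumour suppressor and cell cycle genes had 9 of 35 islands higher in the clones than in MEF and none lower (the same adjusted over the list alone, and 6 and 2 with medians set equal). This was a smaller share than the 5563 of 18416 called higher over all islands. Cdkn2a, a locus that restrains the cell cycle, rose by 2.48 log2, to 5.82 ± 0.50 (SD, n = 5) from 3.34 in MEF, and TS had 5.88. The Wnt inhibitor genes Sfrp2 and Dkk1 rose by 2.64 and 2.60 and the cadherin gene Cdh13 by 2.11. The list had a median of 0.08 and a mean of -0.01 relative to all islands and was not called (adjusted p = 0.82, negative camera direction). Against TS no island of it was called in limma or adjusted over the list alone (adjusted p = 0.75). At Gstp1, a detoxification gene, TS had 5.75 and the clones 3.66 ± 0.97 (adjusted p = 0.17).

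Blood and endothelial genes had 10 of 26 islands higher than in MEF and 1 lower, at Egfl7 (-1.10; the same adjusted over the list alone; 6 and 1 with medians set equal), with an adjusted p of 0.39 for the list. Fli1, an ETS factor gene of endothelium, rose by 2.28, Tal1, a regulator of blood formation, by 2.02, Lsp1 by 1.84 and Esam by 1.81. Against TS no island was called in limma or adjusted over the list alone (adjusted p = 0.22).

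A pattern seen in both tested comparisons was a group of islands with signal in the clones above both TS and MEF. There were 24 islands called higher than both and 2 called lower than both, at Krt7 and Mmp28 (11 and 9 with medians set equal). One group lay on chromosome 9 between 123168391 and 123627229, where Tmem158, Lars2, Sacm1l and Ccr9 rose against both, and Fyco1 lies just beyond. These islands were chosen after their values were seen. Sacm1l stood at 6.35 ± 0.30 log2 in the clones (SD, n = 5), 3.01 in TS and 3.66 in MEF, and Tmem158 at 7.08 ± 0.47, 5.12 and 5.70. The calls of Lars2 and Ccr9 against MEF were lost with medians set equal (adjusted p from 0.0047 to 0.17 and from 0.00047 to 0.050 over their alternatives). Between them, Limd1 stood at 6.32 ± 0.07 in the clones and 5.92 in TS, and Slc6a20a at 6.39 ± 0.21 and 6.01. Limd1 and Slc6a20a were lower in MEF (3.92 and 2.66). A second Lars2 island, at 123370976, stood at 7.96 ± 0.25 in the clones, 7.84 in TS and 7.74 in MEF.

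The hypothesis that rises against TS cluster along chromosomes was tested by permuting the calls over island positions 2000 times. As many as 4 rises within 500000 bp, as observed in 2 overlapping windows on chromosome 9 and in 2 on chromosome 4 that start at 146315748 and 146561517, at the predicted genes Gm17452 and Gm16889, were reached with permutation p = 0.00650, and the permuted median was 2. Calls may therefore cluster, although the permuted maximum was also 4, and a regional change of methylation and a change of copy number in a short segment were not told apart.

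Among trophoblast list genes 6 of 40 had an island called lower in the clones than in MEF, against 66 of 10819 other genes (15% and 0.61%). The list genes had 2.65 kept islands each and the others 1.44, with the kept islands named Fgfr2 counted in. Other genes with as many islands would give 0.418 of 40. The excess depended on the scaling, at 12 of 40 against 3.18 with medians set equal and 14 of 40 against 4.17 with quantile normalization. These counts describe the falls already named and were not tested.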
